A study of Rattus norvegicus with 16 samples.

How the data were processed

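Total RNA was sequenced from synaptoneurosomes of the rostral ventromedial medulla of female SD rats, in 16 libraries: 5 zymosan and 3 saline without re-exposure, and 5 zymosan and 3 saline with re-exposure. Per the labels' protocols, 0.1 ml of 1% zymosan followed 1% protamine on postnatal days 12 to 16, the re-exposed rats were instilled again on day 29, and all tissue was collected on day 30. Per the labels' protocols, RNA was purified with a Qiagen miRNeasy kit, and 300 ng went into Illumina ribosomal RNA-depleted total RNA libraries with fragments of 330 bp, read as paired ends on an Illumina NovaSeq. The characteristics labels give collection days of 30 to 34 for zymosan and 35 to 37 for saline libraries. Within each protocol every library has its own day, rising in the order of the sample labels, and both protocols have the same days. Which of the 2 statements holds could not be settled from the files. Both were used, the first in the tests reported and the second as a covariate in an alternative. Groups were taken from the labels, and the columns of each table were joined to the libraries by protocol, treatment and replicate number.

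The deposited files are 2 tables of genes, 1 per protocol. Per the file headers, the raw columns hold 1 value per library, and these deposited values are estimated counts, of which 51.8% to 68.9% per library are whole numbers, and their totals differ between libraries. The submitters' processing notes name the genome build rn6 and DESeq, without a version or a role for either. The aligner, the counting tool and the use of strand are not given in the sources used here, so it is not known whether reads from overlapping, antisense or near-identical genes were kept apart. The authors also deposited group means of the estimated counts, which are geometric means. The normalized columns of the deposited tables are log2 values: checked on the files, they equal log2 of the raw value over 1 factor per library, floored, minus the gene's median over the 8 libraries of the table, with a largest deviation of 2.6e-06 and 1.4e-06. The authors' fold change columns hold a signed ratio, negative where zymosan is lower. The deposited p-values come with adjusted p-values that equal the Benjamini-Hochberg adjustment over all features of the table. The tables hold features whose highest count is at least 10 in 97.1% of cases without re-exposure and in 100% with re-exposure. In the table without re-exposure 4 values stand at exactly 16777216, all of Rn45s or Rn7sl1, in saline replicate 1 (2 values) and zymosan replicates 2 and 5. This was read as an upper limit of the values, so the totals of these 3 libraries and their shares of Rn45s and Rn7sl1 are lower bounds. Blank cells were read as 0. Symbols turned into dates by a spreadsheet (23) were repaired by gene ID.

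The estimated counts were rounded to whole numbers. Rn45s and Rn7sl1, which took 29.3% to 36.8% of counts without re-exposure and 6.1% to 11% with re-exposure, were left out of library sizes and tests. Low counts were filtered with edgeR's filterByExpr, which left 13051 genes without re-exposure, and 12578 with re-exposure and in the fit of all libraries, which used features in both tables. CPM were computed with TMM factors. Tests used edgeR 4.0.16, quasi-likelihood, with Benjamini-Hochberg adjustment and a threshold of 0.05, in R 4.3.3. Each protocol was fitted alone for zymosan against its saline group. A fit of all 16 libraries as 4 groups gave the difference between the zymosan effects and the comparisons across protocols, and its CPM differ slightly from those of the fits by protocol. Fold changes are given on the log2 scale with standard errors from the fit. The biological coefficient of variation was 10.7% without and 9.7% with re-exposure.

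Gene lists (47, with 1079 entries) and a panel of 14 genes were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives not marked below as later. Lists with at least 5 tested members were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated. Members were also counted after adjustment over the list alone. Named genes were, for each zymosan comparison, the 10 largest rises and 10 largest falls among genes that passed, had a mean of at least 5 CPM, no overlap between groups and a symbol that is not a placeholder. To these were added the 10 list genes with the smallest p, the panel, up to 4 members with the smallest p for each list described, and for other comparisons the 10 genes with a symbol and the smallest p.

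The steps were tested on simulated counts drawn from the means and depths of the real libraries, with 100 genes changed 1.5-fold and 100 changed 2-fold. For the zymosan comparisons against saline and for their difference, a list of 40 further genes raised 1.5-fold was added. For zymosan without re-exposure 70 and 83 of the 100 were called and 33 of the list, with 13 unchanged genes among 199 calls. With re-exposure 75 and 87 were called and 38 of the list, with 7 unchanged genes among 207 calls. For the difference 59 and 86 were called and 23 of the list, with 13 unchanged genes among 181 calls. Camera called the raised list in all 3, and 1 other list for the difference. Genes were drawn independently, so this does not test camera on genes that vary together. Over other splits of the real libraries camera called a median of 8 lists without re-exposure, 10 with re-exposure and 9 for the difference. Between the saline groups 79 and 89 were called, and between the zymosan groups 85 and 95. Libraries were checked for duplicates in 26 pairs within groups, and none was found (chi-square per degree of freedom from 7.5 to 52.4).

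Alternatives were RLE factors, library totals, no filter, a mean of at least 5 CPM, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, 1 surrogate variable from sva 3.50.0, the labelled collection day as a covariate, the replicate number as a block, all libraries in 1 fit, a raw p with a 1.5-fold threshold, camera with an estimated correlation, fry, and leaving out each library in turn. Later additions, made after the data were seen, were the other saline group as control, Rn45s and Rn7sl1 kept, genes with a blank cell left out, library totals for lists and named genes, and a count of list members that passed under each normalisation. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. Gene length and GC content were not tested, since no rn6 genome was at hand.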

Results

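RNA was sequenced from synaptoneurosomes, a preparation of pinched-off synaptic endings, made from the rostral ventromedial medulla of female SD rats. This brainstem area holds serotonergic neurons, and its descending projections raise or lower pain signals in the spinal cord. Pups were given protamine and then zymosan, a yeast cell-wall preparation that inflames the bladder, through the urethra on postnatal days 12 to 16. Control pups were given saline. The labels name protamine for the zymosan groups only, so an effect of zymosan cannot be told apart from one of protamine. In the protocol without re-exposure nothing further was instilled, and in the protocol with re-exposure zymosan or saline was instilled again on day 29. Each protocol had 5 zymosan and 3 saline libraries, 16 in all. The design set each zymosan group against its own saline group, with attention to genes of synaptic transmission, and the series title concerns the added effect of re-exposure. The labels number the libraries within a group and do not say that each came from a separate animal, so the p-values measure the spread between these libraries, which may be technical.

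Total estimated counts per library ran from 65.2 M to 107 M without re-exposure, where values of Rn45s and Rn7sl1 at an apparent upper limit make the 107 M a lower bound, and from 20.0 M to 63.9 M with re-exposure. The ribosomal RNA precursor Rn45s and the signal recognition particle RNA Rn7sl1 together took 29.3% to 36.8% of the counts without re-exposure and 6.1% to 11% with re-exposure, and both were left out of library sizes and tests. The protocol text gives collection on day 30 for all rats. The per-sample labels instead run from day 30 to 34 over the zymosan libraries and from day 35 to 37 over the saline libraries of each protocol. By those labels day and treatment do not overlap. Every library of a protocol has its own labelled day, rising in the order of the sample labels.

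The 3 re-exposed saline libraries stood apart from all others. On the first principal component, which carried 60.3% of the variance, they scored from 66.3 to 69.4, while the other 13 libraries scored from -34.7 to -0.8. Spearman correlations between libraries of the same group were at least 0.991. Between re-exposed saline and the other groups they ran from 0.924 to 0.963, and between all other pairs of groups from 0.983 to 0.994.

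**Figure D1:**
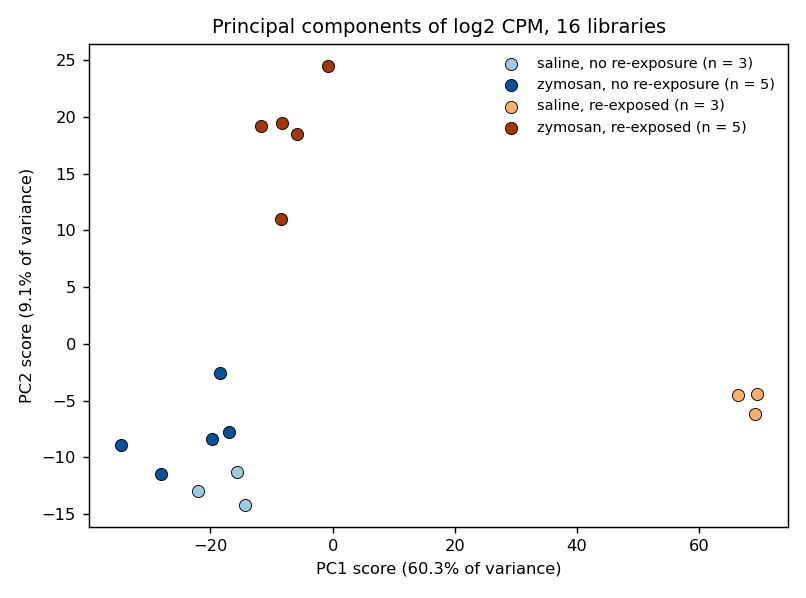
Scores of the 16 libraries on the first principal component (x axis, 60.3% of the variance) and the second (y axis, 9.1%), computed on log2 CPM, with 1 point per library coloured by group. The 3 re-exposed saline libraries score from 66.3 to 69.4 on the first component and the other 13 from -34.7 to -0.8.

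The first comparison asked how synaptoneurosome RNA of rats given zymosan as pups, without re-exposure, differed from that of saline controls. Immediate early genes and glucocorticoid response genes were lower with zymosan, Hox genes were lower, and genes of forebrain position and of the choroid plexus and ependyma were higher. These 5 lists passed camera with its preset correlation, and with an estimated correlation their adjusted p were 0.763, 0.378, 0.877, 0.378 and 0.739. Slc6a3 (gene ID 24898), the dopamine transporter, rose from 0.324 ± 0.0805 CPM (SD, n = 3) to 21.7 ± 9.6 CPM (SD, n = 5), a log2 change of 6.11 ± 0.47 (SE; edgeR adjusted p = 3.13e-06). In the same libraries midbrain position genes, examined after the results were seen, had a median of 0.43, with 17 of 22 higher. A difference in the position of the tissue can therefore not be told apart from zymosan for Slc6a3. Dusp1 (gene ID 114856), an immediate early phosphatase of MAP kinases, fell from 159 ± 41.4 to 39 ± 5.69 CPM, a log2 change of -2.02 ± 0.14 (edgeR adjusted p = 1.24e-06).

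EdgeR's quasi-likelihood test called 2004 of 13051 genes at an adjusted p under 0.05, with 878 higher and 1126 lower with zymosan. In the fit of all 16 libraries the balance turned, with 1462 higher and 1067 lower (57.8% higher against 43.8%). Of the 2004 genes, 233 changed more than 2-fold, 119 upwards and 114 downwards. The median absolute log2 change among called genes was 0.42. The groups did not overlap in 2887 of the tested genes, 1758 of them called, where chance gives 3.6%. In the table deposited by the authors, 3204 genes have an adjusted p under 0.05. The count depended on the controls, with 1096 genes without saline replicate 1 and 682 without saline replicate 2, and with the labelled collection day as a covariate it was 58.

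Of 22 immediate early genes tested, 12 fell and 3 rose, with a median log2 change of -0.54 (camera adjusted p = 6.6e-05; adjusted p = 0.763 with an estimated correlation). By adjustment over the list alone, 13 fell and 3 rose. Fosl2, a partner in the AP-1 transcription factor, had a log2 change of -1.56 ± 0.14, Klf4 -1.93 ± 0.19 and Btg2 -1.04 ± 0.13 (edgeR adjusted p = 1.71e-05, 2.92e-05 and 0.000207). Fos, from the fixed panel, fell by 0.65 ± 0.15 (edgeR adjusted p = 0.013), with adjusted p of 0.0574 without saline replicate 1 and 0.0645 without saline replicate 2. Among 22 glucocorticoid response genes 11 fell and 1 rose, with a median of -0.46 (camera adjusted p = 1.71e-06; adjusted p = 0.378 with an estimated correlation), and adjusted over the list alone 15 fell and 1 rose. They included Klf9 (-0.59 ± 0.06), Errfi1 (-0.88 ± 0.10) and Nfkbia (-0.93 ± 0.12), an inhibitor of NF-kB, with edgeR adjusted p of 4.04e-05, 7e-05 and 0.000207. Dusp1 belongs to both lists. Sgk1, a kinase induced by glucocorticoids, fell by 1.50 ± 0.20 (edgeR adjusted p = 0.000324). For Dusp1 the 3 saline libraries without re-exposure, at 135 to 213 CPM in the fit of all libraries, stood apart from the other 13, at 33.8 to 47.9 CPM, and 19 of 22 immediate early genes were lower in re-exposed saline than in this saline group (camera adjusted p = 6.39e-05; adjusted p = 0.536 with an estimated correlation). In the same libraries endothelial and pericyte markers had a median of -0.17, with 2 of 22 falling (camera adjusted p = 0.104), and the Hox genes a median of -0.64.

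The other falls taken by size included Apold1, which is made in endothelium, from 24.7 ± 11.2 CPM in saline to 4.06 ± 1.06 CPM. Its log2 change was -2.59 ± 0.24 (edgeR adjusted p = 1.88e-05). Cyr61 and Ctgf, secreted matrix proteins of 1 family, fell by 2.27 ± 0.16 and 1.39 ± 0.14 (edgeR adjusted p = 1.77e-06 and 5.5e-05). PVR, Klf2 and Slc47a1 had log2 changes of -1.71, -1.42 and -1.46, each with an edgeR adjusted p of 0.00147 or lower.

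Genes that mark position along the brain moved with the zymosan group. Of 11 Hox genes, which are expressed in the hindbrain and spinal cord, 9 fell and 0 rose, with a median of -0.64 (camera adjusted p = 0.000158; adjusted p = 0.877 with an estimated correlation). The count was the same adjusted over the list alone, and fry did not call the list (adjusted p = 0.0666). Hoxd3 fell by 0.62 ± 0.09 and Hoxb4 by 0.68 ± 0.13 (edgeR adjusted p = 0.000528 and 0.00346). Of 9 forebrain position genes 4 rose and 1 fell, with a median of 0.88 (camera adjusted p = 0.0198; adjusted p = 0.378 with an estimated correlation). The count was unaltered adjusted over the list alone. Six3 stood at 4.01 ± 1.24 CPM with zymosan and 0.0531 ± 0.0602 CPM in saline, where the 3 libraries together held 7 counts, and Lhx2 rose by 1.28 ± 0.23 (edgeR adjusted p = 0.00222). The largest rises also held the transcription factors Tcf7l2 (2.96 ± 0.19), Lef1 (2.86 ± 0.20), Sox14 (2.30 ± 0.26) and Otx2 (2.22 ± 0.25), with edgeR adjusted p from 1.24e-06 to 0.000113. Among 13 choroid plexus and ependymal markers 6 rose and 1 fell, with a median of 0.80 (camera adjusted p = 0.000728; adjusted p = 0.739 with an estimated correlation). With p adjusted over the list alone 10 rose and 1 fell. Otx2 belongs to that list, and Mfrp rose by 1.76 ± 0.46 (edgeR adjusted p = 0.0203), with an adjusted p of 0.052 without saline replicate 3.

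Among synaptic genes, postsynaptic density genes were higher, with 7 of 32 rising and 1 falling and a median of 0.14 (camera adjusted p = 0.00207; adjusted p = 0.877 with an estimated correlation). Adjusted over the list alone 10 rose and 2 fell, and fry did not call the list (adjusted p = 0.0591). Nrgn, a calmodulin-binding postsynaptic protein, rose from 26.0 ± 4.27 to 136 ± 29.7 CPM (log2 change 2.39 ± 0.16, edgeR adjusted p = 1.24e-06). Prkcg rose by 0.72 ± 0.09 and Camk2a by 0.89 ± 0.15 on the log2 scale (edgeR adjusted p = 0.000252 and 0.00154). Ddn, Gda and Fibcd1 rose by 1.70, 1.92 and 1.58. Genes of glutamate release and uptake were lower, with 5 of 11 falling and 0 rising and a median of -0.23 (camera adjusted p = 0.016; adjusted p = 0.656 with an estimated correlation). When adjusted over the list alone, 6 fell. They included the glial transporter gene Slc1a2 (-0.54 ± 0.11) and the glutaminase gene Gls (-0.48 ± 0.09), with edgeR adjusted p of 0.00593 and 0.00393. These groups moved in libraries with the Hox median of -0.64 given above.

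GABA-A receptor subunits moved both ways, with 4 rising and 3 falling of 15 (camera adjusted p = 0.819). Gabra1, the alpha1 subunit, rose from 123 ± 16.3 to 241 ± 41.3 CPM, a log2 change of 0.97 ± 0.12 (edgeR adjusted p = 0.000251). Gad1, which makes GABA, rose by 0.48 ± 0.10 (edgeR adjusted p = 0.00521), and the vesicular transporter Slc32a1 changed by 0.11 ± 0.07 (edgeR adjusted p = 0.311). Grin1, the obligate NMDA receptor subunit, rose by 0.29 ± 0.09 (edgeR adjusted p = 0.0448), a call lost without zymosan replicate 1 or 3 or saline replicate 1 or 2 (adjusted p from 0.0676 to 0.206). The serotonin receptor gene Htr5b fell by 1.08 ± 0.08 and the neuropeptide gene Trh by 1.03 ± 0.09 (edgeR adjusted p = 3.13e-06 and 5.49e-06). The long noncoding RNA Snhg11 fell by 1.07 ± 0.10 (edgeR adjusted p = 1.34e-05). The serotonergic genes Tph2 and Slc6a4 changed by -0.06 ± 0.17 and 0.44 ± 0.25 (edgeR adjusted p = 0.851 and 0.247), with 0.0362 for Slc6a4 without zymosan replicate 4. The opioid receptors Oprm1 and Oprk1, the cannabinoid receptor Cnr1 and the vesicular glutamate transporter Slc17a6 had log2 changes from -0.03 to 0.09 (edgeR adjusted p from 0.67 to 0.94). Bdnf, Trpv1 and Tacr1 changed by -0.34 ± 0.12, -0.39 ± 0.20 and 0.25 ± 0.09 (edgeR adjusted p = 0.064, 0.197 and 0.0702). Leaving out saline replicate 3 gave Bdnf an adjusted p of 0.0142, and leaving out zymosan replicate 5 gave Tacr1 0.0237.

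Neuron markers were lower, with 8 of 17 falling and 0 rising and a median of -0.20 (camera adjusted p = 0.0198; adjusted p = 0.378 with an estimated correlation), among them the neurofilament gene Nefm (-1.12 ± 0.14, edgeR adjusted p = 0.000207). Cholesterol synthesis genes were lower, with 7 of 20 falling and 1 rising and a median of -0.20 (camera adjusted p = 0.0243; adjusted p = 0.912 with an estimated correlation), and the adjusted p was 0.0528 without zymosan replicate 3 and 0.06 without saline replicate 2. Of 71 cytosolic ribosomal protein genes 7 rose and 0 fell, with a median of 0.08 (camera adjusted p = 0.0162; adjusted p = 0.912 with an estimated correlation). Of 73 nuclear-encoded respiratory chain genes 5 rose and 0 fell, with a median of 0.07 (camera adjusted p = 0.0294; adjusted p = 0.912 with an estimated correlation), but adjusted over the list alone 0 of them passed. Adjusted over each list alone, 9 neuron markers fell and 2 rose, 11 cholesterol genes fell and 1 rose, and 6 ribosomal genes rose. The ribosomal call was lost without zymosan replicate 5 (0.0887) or saline replicate 1 (0.173) or 2 (0.0613), and the respiratory call without zymosan replicate 5 (0.219) or saline replicate 2 (0.244) or with a mean of at least 5 CPM (0.0631). Fry called none of the cholesterol, ribosomal and respiratory lists (adjusted p = 0.0666, 0.446 and 0.446). In the same libraries choroid plexus and ependymal markers had a median of 0.80, forebrain position genes 0.88 and Hox genes -0.64, and microglia, astrocyte and oligodendrocyte markers had medians of 0.06, -0.13 and -0.07 (camera adjusted p = 0.628, 0.456 and 0.299).

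The second comparison asked the same of rats exposed again on day 29. Genes of serotonergic neurons and of microglia were lower in re-exposed zymosan libraries than in re-exposed saline libraries, and Hox genes and calcium channel genes were higher. Each of these 4 lists had an adjusted p = 0.575 with an estimated correlation. Tph2 (gene ID 317675), which makes serotonin in the brain, fell from 142 ± 29 CPM (SD, n = 3) to 27.5 ± 3.1 CPM (SD, n = 5), a log2 change of -2.37 ± 0.12 (edgeR adjusted p = 2.67e-09). Hoxb5 (gene ID 497987) rose from 6.28 ± 3.11 to 106 ± 5.1 CPM, a log2 change of 4.16 ± 0.20 (edgeR adjusted p = 1.97e-09). Against the saline libraries without re-exposure the same zymosan libraries gave -0.25 for Tph2 and 0.14 for Hoxb5 (edgeR adjusted p = 0.243 and 0.584).

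EdgeR called 8657 of 12578 genes, 4354 higher and 4303 lower with zymosan, and 1747 of them changed more than 2-fold (912 upwards, 835 downwards). The median absolute log2 change among called genes was 0.62. The groups did not overlap in 8098 genes, where chance gives 3.6%. In the table deposited by the authors, 9043 genes have an adjusted p under 0.05. With saline without re-exposure as the control, an alternative chosen after the re-exposed saline libraries were seen to stand apart, 4184 genes were called, 3005 of them among the 8657, and 187 changed more than 2-fold. With the labelled collection day as a covariate 5441 genes were called.

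**Figure D2:**
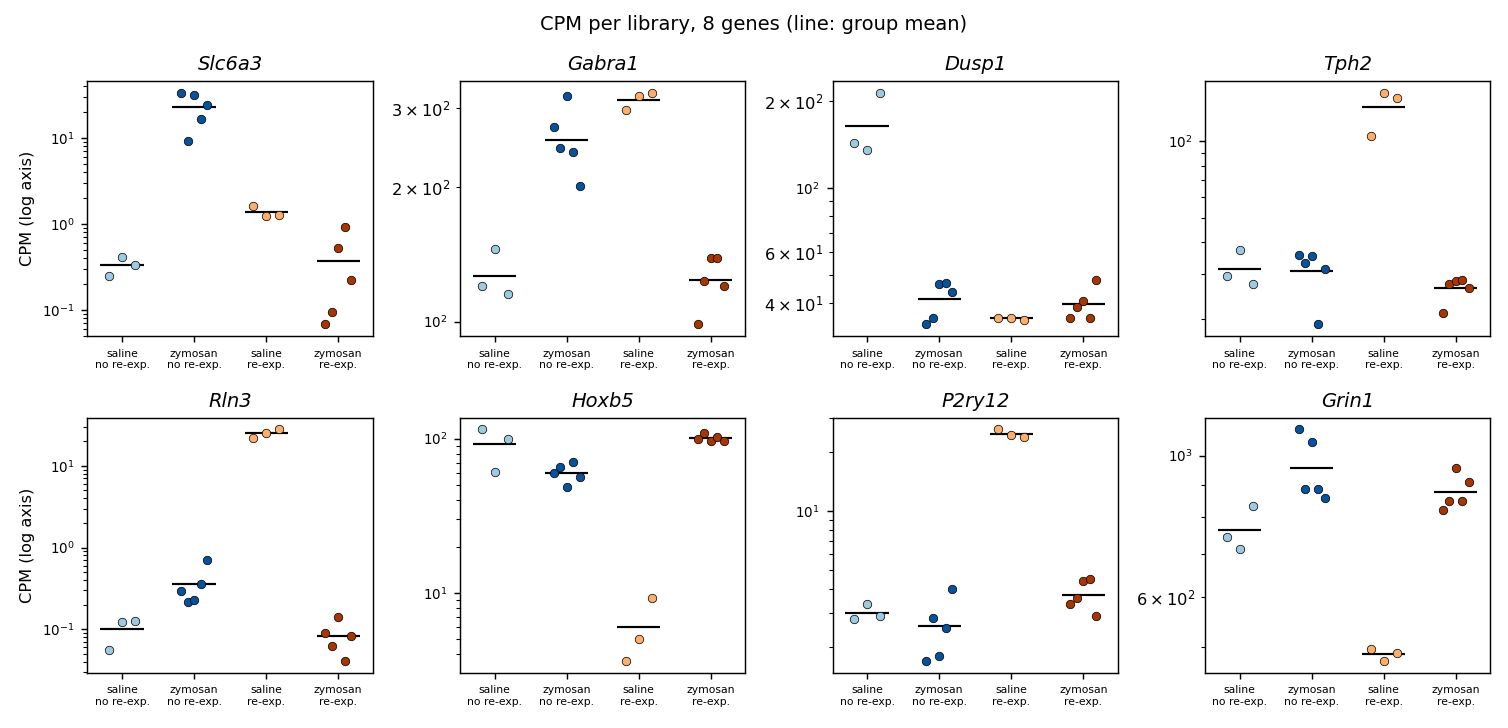
CPM of 8 genes in each of the 16 libraries (y axis, log scale), by group on the x axis, with 1 point per library and a line at the group mean. In Tph2, Rln3, Hoxb5, P2ry12 and Grin1 the 3 re-exposed saline libraries lie apart from the libraries of the other groups, and in Slc6a3 the 5 zymosan libraries without re-exposure do.

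For the 11 lists called in this comparison, the counts adjusted over the list alone were the same as over all genes, except 65 respiratory chain and 58 ribosomal genes lower. Of 11 genes of serotonergic neurons 10 fell and 1 rose, with a median of -1.53 (camera adjusted p = 0.00102; adjusted p = 0.575 with an estimated correlation). Slc18a2, the vesicular monoamine transporter, changed by -2.41 ± 0.10, Ddc by -1.72 ± 0.08 and the serotonin transporter Slc6a4 by -1.68 ± 0.14 (edgeR adjusted p = 9.21e-10, 1.34e-09 and 1.14e-07). Lmx1b, a transcription factor of these neurons, rose by 2.03 ± 0.15 (edgeR adjusted p = 7.13e-08). Among single genes of the catecholamine list, Slc6a2 changed by -4.37 ± 0.14, Dbh by -2.70 ± 0.09 and Th by -1.81 ± 0.08 (edgeR adjusted p = 2.92e-10, 3.56e-10 and 1.32e-09). The list as a whole, with 7 of 17 rising and 5 falling and a median of 0.36, was not called (camera adjusted p = 0.58). Rln3, a neuropeptide of the nucleus incertus in the pons, stood at 26.3 ± 3.17 CPM in saline and 0.0872 ± 0.0386 CPM with zymosan, where the 5 libraries held 17 counts in total (log2 change -8.29 ± 0.19, edgeR adjusted p = 6.41e-12). Against saline without re-exposure the serotonergic list had a median of -0.25 (camera adjusted p = 0.136), and Slc6a2, Slc18a2, Dbh and Th changed by -1.02, -0.49, -0.09 and 0.29.

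All 11 Hox genes rose, with a median of 1.92 (camera adjusted p = 9.67e-05; adjusted p = 0.575 with an estimated correlation), and all 11 passed with TMM factors, RLE factors and library totals. Hoxc5 rose by 3.08 ± 0.18 and Hoxb4 by 2.57 ± 0.19 (edgeR adjusted p = 6.25e-09 and 5.32e-08). Hoxb8 ran from 13.6 to 35.8 CPM in the zymosan libraries, and of the 3 saline libraries 2 were at 0 and 1 at 2.24 CPM. The fitted log2 change of Hoxb8, 5.78 ± 0.72, therefore rests on few saline counts (edgeR adjusted p = 7.37e-06). Other rises taken by size were Cdh3 (2.85 ± 0.19), Shisa8 (2.49 ± 0.23), Lbx1 (2.45 ± 0.13), Msx1 (2.27 ± 0.34), Pou6f1 (2.21 ± 0.10) and Col27a1 (2.13 ± 0.16), with edgeR adjusted p from 1.32e-09 to 4.47e-05. Against saline without re-exposure the Hox median was 0.14 (camera adjusted p = 0.931), Msx1 rose by 1.01 (edgeR adjusted p = 0.013) and Col27a1 changed by -0.40 (edgeR adjusted p = 0.0532). Cdh3, Shisa8, Lbx1 and Pou6f1 changed by 0.62, 0.35, 0.10 and 0.04 with that control (edgeR adjusted p from 0.0555 to 0.778).

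**Figure D3:**
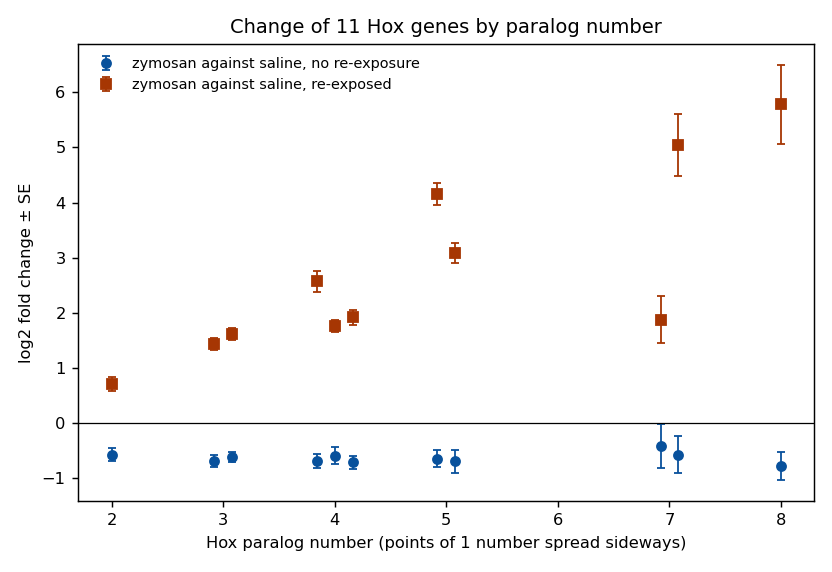
Log2 fold change of 11 Hox genes with zymosan (y axis, bars are SE) against their paralog number (x axis) in both protocols, with n = 5 zymosan and 3 saline libraries per protocol. After re-exposure the changes run from 0.71 for Hoxa2 to 5.78 for Hoxb8, and without re-exposure from -0.78 to -0.42.

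Microglia markers were lower, with 15 of 18 falling and 1 rising and a median of -1.32 (camera adjusted p = 0.000169; adjusted p = 0.575 with an estimated correlation). P2ry12, a purinergic receptor of resting microglia, fell from 26.2 ± 1.21 to 3.90 ± 0.707 CPM (log2 change -2.75 ± 0.13, edgeR adjusted p = 1.36e-09), and Gpr34 and Hexb changed by -2.30 ± 0.14 and -1.26 ± 0.06 (edgeR adjusted p = 8.33e-09 and 2.35e-09). Cd53, a leukocyte tetraspanin, fell by 2.46 ± 0.14 (edgeR adjusted p = 8.19e-09). Astrocyte markers were lower, with 13 of 16 falling and 1 rising and a median of -0.60 (camera adjusted p = 0.0103; adjusted p = 0.575 with an estimated correlation), including Acsbg1 (-0.99 ± 0.08) and the glutamate transporter gene Slc1a3 (-0.85 ± 0.07), with edgeR adjusted p of 8.13e-08 and 7.99e-08. Oligodendrocyte and endothelial markers had medians of 0.17 and -0.02 (camera adjusted p = 0.703 and 0.995). Against saline without re-exposure microglia markers were instead higher, with a median of 0.32 (camera adjusted p = 0.0481; adjusted p = 0.735 with an estimated correlation), P2ry12 at 0.32 and Cd53 at 0.76, and the astrocyte median was -0.08.

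Of 21 voltage-gated calcium channel genes 18 rose and 1 fell, with a median of 0.70 (camera adjusted p = 0.000257; adjusted p = 0.575 with an estimated correlation). Cacna1g, the T-type Cav3.1 subunit, rose by 1.69 ± 0.08 and Cacna1h by 1.10 ± 0.08 (edgeR adjusted p = 1.35e-09 and 5.06e-08). Of 17 ionotropic glutamate receptor genes 13 rose and 3 fell, with a median of 0.56 (camera adjusted p = 0.0286; adjusted p = 0.575 with an estimated correlation), with Grin1 at 0.84 ± 0.07, Grin2a at 1.04 ± 0.09 and Gria4 at -0.80 ± 0.06 (edgeR adjusted p = 8.17e-08, 1.51e-07 and 9.96e-08). Postsynaptic density genes were higher, with 18 of 32 rising and 6 falling and a median of 0.40 (camera adjusted p = 0.0323; adjusted p = 0.798 with an estimated correlation). Dlg4, which encodes PSD-95, rose by 1.18 ± 0.06 and Syngap1 by 1.39 ± 0.08 (edgeR adjusted p = 2.74e-09 and 7.45e-09). Neurotrophin signalling genes were higher, with 9 of 14 rising and 1 falling and a median of 0.39 (camera adjusted p = 0.0323; adjusted p = 0.575 with an estimated correlation), including Ngfr (1.11 ± 0.12, edgeR adjusted p = 1.61e-06). Against saline without re-exposure the medians of these 4 lists were -0.13, -0.10, -0.10 and -0.05 in the same order, each opposite in sign. Of these only the postsynaptic density list was called (camera adjusted p = 0.0126). With an estimated correlation camera called 0 lists against this control (smallest adjusted p 0.319). The potassium channel gene Kcna6, also among the smallest p, rose by 1.37 ± 0.06 and the clock-controlled gene Tef by 1.25 ± 0.06 (edgeR adjusted p = 1.34e-09 and 1.32e-09). With saline without re-exposure as the control, Kcna6 and Tef changed by 0.18 and 0.07 (edgeR adjusted p = 0.0602 and 0.384).

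Immediate early genes were higher, with 14 of 22 rising and 3 falling and a median of 0.49 (camera adjusted p = 0.0433; adjusted p = 0.575 with an estimated correlation). Arc rose by 1.30 ± 0.10 and Egr1 by 1.27 ± 0.20 (edgeR adjusted p = 9.62e-08 and 6.5e-05), and Fos by 0.67 ± 0.13 (edgeR adjusted p = 0.000409). Without zymosan replicate 3 the immediate early, postsynaptic density and neurotrophin lists missed the threshold (adjusted p = 0.0733, 0.0516 and 0.0607), as did the immediate early and neurotrophin lists among genes with a mean of at least 5 CPM (0.222 and 0.0508). Of 73 respiratory chain genes 64 fell and 0 rose, with a median of -0.48 (camera adjusted p = 1.65e-10; adjusted p = 0.575 with an estimated correlation), and of 71 ribosomal protein genes 57 fell and 0 rose, with a median of -0.50 (camera adjusted p = 3.69e-09; adjusted p = 0.612 with an estimated correlation). Ndufs6 fell by 1.56 ± 0.08 and Rpl30 by 1.55 ± 0.07 (edgeR adjusted p = 2.93e-09 and 1.25e-09). Against saline without re-exposure the medians were -0.57 for immediate early genes (camera adjusted p = 3.02e-09), 0.24 for the respiratory chain (1.69e-06) and 0.12 for ribosomal proteins (0.00318), with adjusted p of 0.319, 0.735 and 0.837 with an estimated correlation, and Fos changed by -0.91 (edgeR adjusted p = 0.000167). Ribosomal protein genes have many pseudogene copies, so their counts are uncertain.

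In the remaining fixed panel Gabra1 fell by 1.35 ± 0.09 and Gad1 by 0.64 ± 0.06 on the log2 scale (edgeR adjusted p = 2.87e-08 and 2.45e-07), and Slc17a6 by 0.44 ± 0.08 (edgeR adjusted p = 0.000305). GABA-A subunits as a list, with 9 of 15 falling and 4 rising, were not called by camera (adjusted p = 0.117) but were by fry (adjusted p = 0.00225). Trpv1, the capsaicin receptor, rose by 1.04 ± 0.24 and Tacr1, the substance P receptor, by 0.47 ± 0.09 (edgeR adjusted p = 0.00154 and 0.000421). Oprk1 rose by 0.22 ± 0.09 (edgeR adjusted p = 0.0411), a call lost without zymosan replicate 1, 4 or 5 or saline replicate 1 or 3 (adjusted p from 0.0659 to 0.127). Oprm1, Cnr1, Slc32a1 and Bdnf had changes from -0.13 to 0.00 that did not pass (edgeR adjusted p from 0.102 to 0.984), with 0.027 for Slc32a1 without zymosan replicate 3. Slc17a8, Sult1d1 and Ccdc81 changed by -2.50 ± 0.20, -2.59 ± 0.23 and -2.31 ± 0.20 (edgeR adjusted p = 1.14e-07, 2.61e-07 and 2.09e-07). Against saline without re-exposure Gabra1, Gad1, Trpv1 and Sult1d1 changed by -0.03, 0.04, -0.31 and 0.86 (edgeR adjusted p = 0.853, 0.764, 0.235 and 0.0564). With the same control Tacr1, Oprk1 and Slc17a6 changed by 0.01, 0.05 and -0.11 (edgeR adjusted p = 0.955, 0.745 and 0.379). Slc17a8 and Ccdc81 changed by -0.31 and 0.34 (edgeR adjusted p = 0.312 and 0.272).

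**Figure D4:**
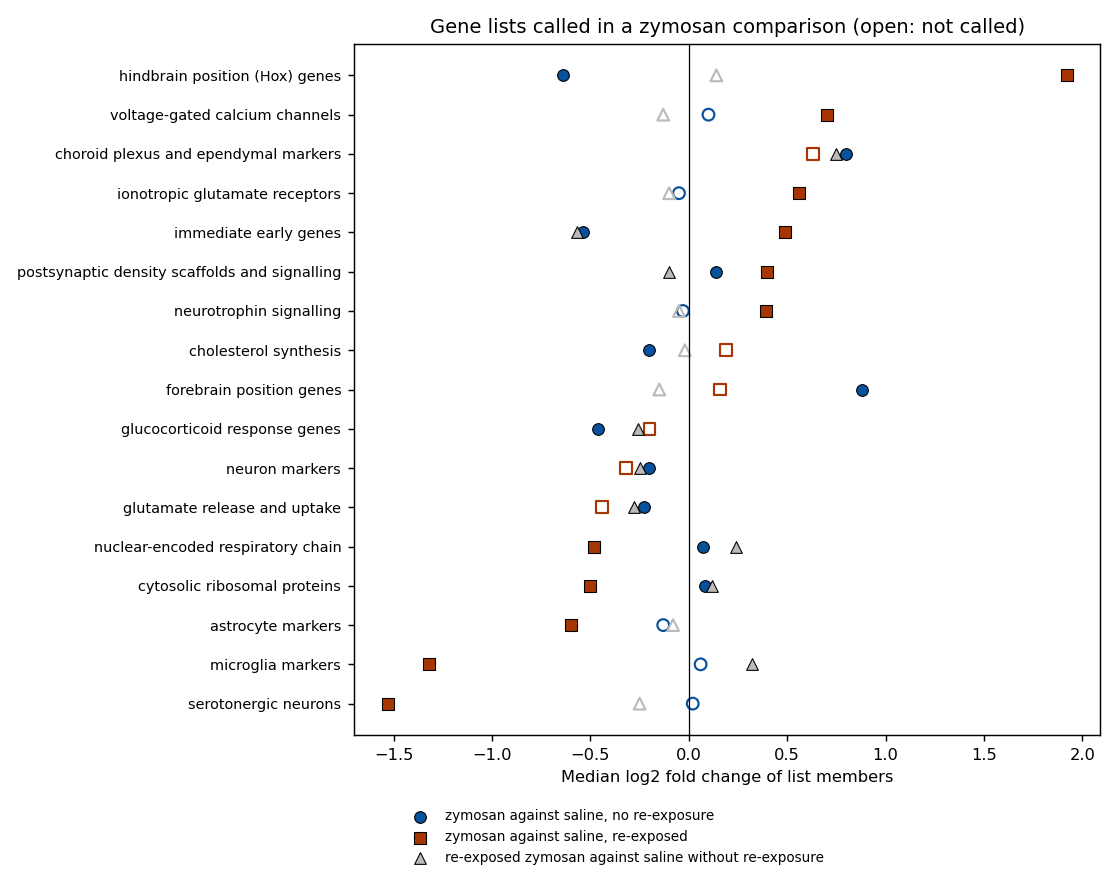
Median log2 fold change of list members (x axis) for the 17 gene lists called by camera in either zymosan comparison (y axis), with re-exposed zymosan against saline without re-exposure added as triangles; filled symbols passed an adjusted p under 0.05. The immediate early gene medians are -0.54 without re-exposure, 0.49 with re-exposure and -0.57 with the other saline group as control.

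The difference between the zymosan effects was tested directly in a fit of all 16 libraries, and 7231 of 12578 genes passed (3639 higher after re-exposure, 3592 lower). No group had saline as pups and zymosan on day 29. An added effect of re-exposure can therefore not be told apart from an effect of the day 29 zymosan alone. The genes with the smallest p mostly carried a low or high level in the re-exposed saline group. Rims4, an active-zone protein, stood at 49.4 ± 2.75 and 41.6 ± 3.1 CPM in saline and zymosan without re-exposure and at 10.1 ± 0.811 and 43.9 ± 2.12 CPM with re-exposure (difference 2.35 ± 0.11, edgeR adjusted p = 1.25e-11). Unc5b, a netrin receptor, and Adra1d, an adrenergic receptor, differed by 2.14 ± 0.11 and 1.98 ± 0.11 (edgeR adjusted p = 2.99e-11 and 4.29e-11). Rln3 differed by -10.23 ± 0.52 (edgeR adjusted p = 2.77e-11). Pax7 stood at 0.109 and 6.10 CPM without and at 1.49 and 0.148 CPM with re-exposure in saline and zymosan (difference -9.22 ± 0.51, edgeR adjusted p = 5.73e-11). Tmcc2, Kcng1, Miat, Hoxb5 and Map3k11 differed by 1.66, 2.59, 2.49, 4.78 and 1.52. With the labelled collection day as a covariate 3809 genes passed.

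By list, each with an adjusted p of 0.553 or more with an estimated correlation, the difference was positive for Hox genes (11 of 11, median 2.60), immediate early genes (16 of 22, 1.32), ionotropic glutamate receptors (13 of 17, 0.61), calcium channels (14 of 21, 0.58), cholesterol synthesis (11 of 20, 0.42) and neurotrophin signalling (8 of 14, 0.32). It was negative for serotonergic genes (10 of 11, -1.49), microglia (15 of 18, -1.34), ribosomal proteins (59 of 71, -0.64), the respiratory chain (68 of 73, -0.56) and astrocyte markers (10 of 16, -0.42). Camera adjusted p ran from 9.35e-15 to 0.0339 over these 11 lists. Adjusted over the list alone the counts were the same, except 60 ribosomal and 70 respiratory chain genes. The neurotrophin call was lost without re-exposed zymosan replicate 3 (0.0683) or with a mean of at least 5 CPM (0.0641), and the astrocyte call without re-exposed saline replicate 1 (0.0606). Among immediate early genes Dusp1 and Fosb differed by 2.15 ± 0.19 and 2.61 ± 0.31 (edgeR adjusted p = 1.67e-08 and 7.21e-07). In the cholesterol list Ldlr and Dhcr24 differed by 1.46 ± 0.11 and 1.30 ± 0.11 (edgeR adjusted p = 2.19e-09 and 6.59e-09).

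The zymosan effects of the 2 protocols rest on separate libraries. Over the 12565 genes in both fits, 850 rose and 1103 fell without re-exposure. Of these, 491 rose and 433 fell in both protocols, against 294.5 and 377 for independent lists, while 154 rose without and fell with re-exposure and 314 the reverse, against 290.5 and 382.1. Of the 1392 genes called in both, 924 (66.4%) had the same direction. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.13 and a Spearman correlation of 0.21.

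Between the saline groups, re-exposed against not, genes of the postsynaptic density, vesicle release, calcium and potassium channels and the immediate early genes were lower in the re-exposed saline libraries, and microglial, ribosomal and respiratory genes were higher. The lowest adjusted p of any list with an estimated correlation was 0.536. EdgeR called 8690 of 12578 genes, 4358 higher and 4332 lower, and 2411 changed more than 2-fold. Rims4 was lower, with a log2 change of -2.27 ± 0.09, as were Unc5b (-2.06 ± 0.09) and the long noncoding RNA Miat (-2.52 ± 0.12), and Rln3 was higher, at 8.01 ± 0.34 (edgeR adjusted p from 4.82e-13 to 1.57e-12). The proteasome genes Psmd6 and Psma4 were higher, at 1.57 ± 0.07 and 1.76 ± 0.08, and Tmcc2, Tnrc18, Adap1 and Dot1l lower, at -1.78, -1.96, -1.52 and -2.31. Of 16 called lists, respiratory chain genes (67 of 73 higher, median 0.73), ribosomal proteins (62 of 71, 0.68) and microglia markers (16 of 18, 1.54) were higher, and Hox genes (11 of 11 lower, -1.97), immediate early genes (19 of 22, -1.66), calcium channels (16 of 21, -0.92), potassium channels (28 of 40, -0.51), postsynaptic density genes (20 of 32, -0.54) and vesicle release genes (25 of 44, -0.30) lower. Camera adjusted p for these 9 ran from 2.72e-14 to 0.00545, and from 0.536 to 0.609 with an estimated correlation. GABA-A subunits, with 10 of 15 higher and 4 lower, were not called (camera adjusted p = 0.142). The counts adjusted over the list alone were the same, except 63 ribosomal genes. With library totals in place of TMM factors the median of all genes was 0.109, so these changes are relative to it. The labels give no batch that the protocols share, so protocol and batch cannot be told apart here or in the next comparison.

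Between the zymosan groups, the re-exposed libraries had lower Pax7, En2 and Lef1, transcription factors of position, and lower Slc6a3. EdgeR called 4491 of 12578 genes, 2347 higher and 2144 lower, and 120 changed more than 2-fold. Pax7 had a log2 change of -5.37 ± 0.29, En2 -3.31 ± 0.20, Tcf7l2 -3.05 ± 0.18, Slc6a3 -6.01 ± 0.42 and Lef1 -2.29 ± 0.16 (edgeR adjusted p from 1.76e-10 to 6.24e-09). Sox14, Tal1, Gas7, Itpr1 and the RNase MRP RNA Rmrp were lower, at -2.56, -1.93, -1.03, -0.97 and -3.01. The fall of Rmrp was not particular to zymosan, since its zymosan effects did not differ between protocols (-0.25 ± 0.27, edgeR adjusted p = 0.43). Rn45s and Rn7sl1 also took a smaller share of counts in all re-exposed libraries, saline included. For these RNAs too, protocol and batch cannot be told apart. Of 13 called lists, postsynaptic density genes were lower (24 of 32, median -0.30), with Nrgn at -1.81 ± 0.16, and so were vesicle release genes (23 of 44, -0.20), while Hox genes (10 of 11, 0.75) and interferon and MHC genes (14 of 26, 0.51) were higher. Camera adjusted p for these 4 ran from 1.33e-09 to 0.00231, and each had an adjusted p = 0.649 with an estimated correlation. List counts adjusted over the list alone were the same, except 25 vesicle release genes lower and 17 interferon and MHC genes higher. With library totals 5749 genes were called, 85.0% of them higher against 52.3% with TMM factors, and the median of all genes was 0.166. With the labelled collection day as a covariate 2412 genes were called.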

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

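The tests of explanations in this part were chosen after the results they bear on were seen. The counts over other splits of the samples were part of the plan.

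Among 102 groups of 5 libraries examined for a single library far from the rest, 8 held one, and chance gives about 1 in 20. The measure is the gap to the nearest other library as a share of the group's range. Without re-exposure, zymosan replicate 3 was highest for Six3 (6.18 CPM, others 3.18 to 3.78, share 0.801) and Gad1 (359 CPM, others 268 to 285, 0.811). Zymosan replicate 4 was lowest for Tph2 (17.8 CPM, others 29.7 to 33.6, 0.75), and zymosan replicate 1 highest for Trpv1 (2.26 CPM, others 1.39 to 1.63, 0.722). With re-exposure, zymosan replicate 4 was lowest for Lbx1 (14.9 CPM, others 18.3 to 19.6, 0.736) and highest for the microglia marker mean (3.13 log2 CPM, others 2.86 to 2.94, 0.717). Zymosan replicate 3 was highest for Cacna1g (221 CPM, others 182 to 191, 0.775) and for the astrocyte marker mean (8.17 log2 CPM, others 7.94 to 7.98, 0.831).

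The zymosan effect differed between the protocols in 7231 genes by edgeR's test of the difference, and in 52 of the 63 named genes tested for it. The 10 genes with the smallest p had differences of 2.35 (Rims4), -10.23 (Rln3), 2.14 (Unc5b), 1.98 (Adra1d), -9.22 (Pax7), 1.66 (Tmcc2), 2.59 (Kcng1), 2.49 (Miat), 4.78 (Hoxb5) and 1.52 (Map3k11) on the log2 scale. The 11 lists called for a difference had medians of 0.61 (ionotropic glutamate receptors), -1.49 (serotonergic neurons), 0.58 (calcium channels), 0.32 (neurotrophin signalling), 1.32 (immediate early genes), -0.42 (astrocytes), -1.34 (microglia), 2.60 (Hox genes), -0.64 (ribosomal proteins), -0.56 (respiratory chain) and 0.42 (cholesterol synthesis).

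Chance assignment of libraries to groups was examined over other splits of the same libraries. For zymosan without re-exposure, 1 of 56 splits, the real one, gave as many as 2004 genes, and the highest other gave 5. With re-exposure it was 1 of 56 for 8657 genes, and the highest other gave 0. If the libraries are independent units, which the labels do not state, chance was excluded for these counts. The same held for the 4491 genes between the zymosan groups (1 of 100 splits, highest other 1681). The 7231 genes of the difference were reached in 1 of 100 splits, but the highest other gave 7076. For the difference, 3 other splits gave 6437, 6503 and 7076 genes, and all 3 kept the re-exposed groups whole while exchanging libraries without re-exposure. This points to a structure of the samples: the count hardly depends on the assignment of the libraries without re-exposure. Chance was therefore not excluded for that part of the difference. The saline groups allow 10 splits, too few for a share under 0.05, with 8690 genes in the real split (1 of 10) and 0 in the highest other. For the numbers of lists chance was not excluded: 15 of 56 splits gave at least 11 lists without re-exposure (highest 17), 24 of 56 with re-exposure (highest 18) and 43 of 100 for the difference (highest 21).

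The Hox genes were lower with zymosan without re-exposure and higher after re-exposure. All 11 Hox genes tested differed between the protocols, which restates the pattern that prompted the test. The test also uses the re-exposed saline group, and against the other saline group the re-exposed zymosan libraries had a Hox median of 0.14. It therefore cannot decide on an effect of neonatal zymosan shared by both protocols. After re-exposure the change grew with paralog number (Spearman rho 0.86, permutation p = 0.001; without re-exposure -0.08, p = 0.81), which re-exposed saline tissue taken further rostral would give. Midbrain position genes would be higher in such saline tissue if it reached that far. After re-exposure they did not go that way (11 of 18 higher with zymosan, median 0.32, exact sign test p = 0.48, with 7 passing higher and 6 lower). These genes cannot place tissue that ends short of the midbrain. The permutation over paralog number and the sign tests of midbrain genes take genes as units, and genes are not independent replicates. Their p-values do not measure the spread between libraries. Rln3, the neuropeptide of the pons named above, stood at 26.3 ± 3.17 CPM in re-exposed saline and 0.0872 ± 0.0386 CPM in re-exposed zymosan libraries. It is a single gene picked for the size of its change. Slc6a2 and Dbh, picked likewise, stood at 44.4 and 121 CPM in re-exposed saline and 2.17 and 18.6 CPM in re-exposed zymosan libraries. Serotonergic genes were also higher in re-exposed saline (10 of 11, with 1 lower). Catecholamine genes went both ways (5 of 17 higher in re-exposed saline, 7 lower). Whether these genes follow the position of the tissue was not tested. The position of the re-exposed saline tissue stays open, as does an effect of zymosan within each protocol. Without re-exposure, midbrain position genes had a median of 0.43 (17 of 22 higher, exact sign test p = 0.017; 9 passed higher and 2 lower), which zymosan tissue taken further rostral would give; 3 of the 26 genes on that list (Gata2, Gata3, Nr4a2) are also in a list fixed earlier, and its most abundant genes, Meis2 and Ebf3, stood at 53.7 and 50.6 CPM with zymosan and 63.6 and 48.6 CPM in saline.

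The re-exposed saline libraries stood apart from the other 13. After thinning all 8 libraries to 17.8 M counts the respiratory chain median was -0.49, against -0.48 before. Thinning keeps each gene's expected share of counts, so this median could hardly move and does not bear on depth. Depth is argued against for re-exposed saline replicates 1 and 2, which held 32.49 M and 42.41 M counts in the tests. They scored 66.3 and 69.4 on the first component, while re-exposed zymosan replicate 3, with 28.61 M, scored -8.5. Processing of the re-exposed table as a whole is argued against by the 120 genes that differed over 2-fold between the zymosan groups, against 2411 between the saline groups. A lower share of neurons with all other cell types raised alike is argued against, since oligodendrocyte and microglia markers moved apart by 1.31 on the log2 scale (permutation p = 8e-05). That permutation shuffled genes, which are not independent replicates. A lower share of neurons beside unequal changes of the other cell types stays open. A handling or library batch of these 3 libraries, which cannot be told apart from their group, and an effect of the second saline instillation both stay open.

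Immediate early and glucocorticoid response genes were lower with zymosan without re-exposure, where the saline group is the one that stands apart for Dusp1 (135 to 213 CPM, against 33.8 to 47.9 CPM in the other 13 libraries, re-exposed saline included). Less endothelial RNA is argued against as the whole cause, since the lower quartile of the endothelial markers was -0.31 and the immediate early median -0.54. Collection day cannot be told apart from treatment: with the labelled day as a covariate the immediate early median was -0.28, 2 of 22 genes passed, and the median standard error went from 0.15 to 0.28. For the glucocorticoid response genes the median was -0.28, 1 gene passed, and the median standard error went from 0.11 to 0.19. An effect of neonatal zymosan and a property of that saline group both stay open.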

How the results depend on the processing

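Single named genes were run under RLE factors, library totals, DESeq2, the replicate block, left-out libraries and, after re-exposure, the other saline control. Under these, 69 of 108 results kept their direction and their side of the threshold. Apart from the exchange of the control group, 100 did so. That exchange was chosen after the data were seen. So were Rn45s and Rn7sl1 kept, blank cells left out and library totals for lists and named genes. The other alternatives, the labelled collection day among them, were not run for named genes. With the day as a covariate, 54 of the 2004 genes called without re-exposure were still called. Gene counts stayed within 1.5 times for RLE factors, library totals, both filter settings, DESeq2, limma-voom, the surrogate variable and all libraries in 1 fit, and also with Rn45s and Rn7sl1 kept and with blank cells left out. In the joint fits the filter removed 0 genes, so leaving it out tests nothing there. The cause was not tested for the values below, except that the day covariate and the left-out libraries leave fewer degrees of freedom.

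With the labelled collection day as a covariate, 58 genes were called without re-exposure, 5441 with re-exposure, 3809 for the difference and 2412 between the zymosan groups. With a raw p under 0.05 and at least 1.5-fold, the counts were 811 and 4664. With an estimated correlation camera called 0, 0 and 0 lists without re-exposure, with re-exposure and for the difference (smallest adjusted p 0.378, 0.575 and 0.553), and fry called 6, 30 and 32. Without re-exposure fry left postsynaptic density (adjusted p = 0.0591), Hox (0.0666), cholesterol (0.0666), ribosomal (0.446) and respiratory chain genes (0.446) uncalled. A mean of at least 5 CPM left uncalled the respiratory chain without re-exposure (0.0631), neurotrophin signalling (0.0508) and immediate early genes (0.222) with re-exposure, and neurotrophin signalling for the difference (0.0641). DESeq2 also called Bdnf and Tacr1 without re-exposure, and library totals left Oprk1 after re-exposure uncalled.

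With saline without re-exposure as the control, 4184 genes were called after re-exposure, and of 39 named genes 7 were unaltered in call, 21 weaker and 11 opposite in sign: Col27a1 -0.40, P2ry12 0.32, Sult1d1 0.86, Cd53 0.76, Ccdc81 0.34, Rpl30 0.25, Th 0.29, Cacna1g -0.20, Gad1 0.04, Trpv1 -0.31 and Fos -0.91. Of the 11 lists 3 were weaker and 8 opposite in median: ionotropic glutamate receptors -0.10, calcium channels -0.13, postsynaptic density -0.10, neurotrophin signalling -0.05, immediate early genes -0.57, microglia 0.32, ribosomal proteins 0.12 and respiratory chain 0.24.

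Leaving out each library in turn gave 682 to 2092 genes without re-exposure, 7759 to 8737 with re-exposure, 6556 to 7377 for the difference, 8093 to 8806 between saline and 3583 to 4546 between zymosan groups, and 8 to 13, 8 to 12 and 10 to 12 lists. The 682 came without saline replicate 2, and 1096 without saline replicate 1. Of 1104 values for named genes 12 lost and 4 gained a call, and of 352 for lists 12 lost it.

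The replicate numbers did not pair the libraries: same-numbered zymosan and saline libraries had correlations of -0.11, 0.13 and 0.16 without and -0.06, 0.05 and -0.11 with re-exposure. With the replicate block the counts were 2270, 7990, 7130, 8581 and 4372 genes, in the order of the ranges above, and 10, 13 and 11 lists, of which 8, 11 and 11 were among those called without the block. Neuron markers, ribosomal proteins and the respiratory chain without re-exposure (adjusted p = 0.0881, 0.21 and 0.357) and Oprk1 with re-exposure (0.18) were not called with it, and Slc6a4 and Tacr1 without re-exposure (0.00333 and 0.0334) were.

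Library totals moved the share of higher calls between the zymosan groups from 52.3% to 85.0% (5749 genes), and the median of all genes from 0.020 to 0.166, and between the saline groups from 0.001 to 0.109. Without re-exposure, the fit of all libraries called 2529 genes, 57.8% higher against 43.8%. Depth limits the re-exposed saline group most, where replicate 3 held 20.0 M counts.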

Other observations

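The lists of GABA-A receptor subunits, opioid genes and neuropeptides were not called by camera in either comparison of zymosan with saline (camera adjusted p = 0.819 and 0.117 for GABA-A subunits, 0.628 and 0.36 for opioid genes, 0.762 and 0.937 for neuropeptides). Fry called the first 2 after re-exposure (adjusted p = 0.00225 and 0.000877). Their members went both ways: after re-exposure 4 of 15 subunits rose and 9 fell, 5 of 8 opioid genes rose and 1 fell, and 14 of 35 neuropeptide genes rose and 12 fell, where 68.8% of all genes passed. Without re-exposure Gabrd rose by 1.22 ± 0.19 and Gabrq, the theta subunit, fell by 0.75 ± 0.10 (edgeR adjusted p = 0.000865 and 0.000244). After re-exposure Gabrq fell by 1.15 ± 0.10 (edgeR adjusted p = 3.07e-07). The delta opioid receptor Oprd1 fell by 0.41 ± 0.12 without and rose by 0.63 ± 0.17 with re-exposure (edgeR adjusted p = 0.0376 and 0.00457). The opioid peptide precursors Pdyn and Penk rose by 1.10 ± 0.14 and 0.44 ± 0.10 after re-exposure (edgeR adjusted p = 6.54e-06 and 0.00196). Without re-exposure Crh fell by 1.13 ± 0.13 and Cck and Vip rose by 1.41 ± 0.20 and 1.52 ± 0.28 (edgeR adjusted p = 0.000105, 0.000441 and 0.00334). After re-exposure 7 of 10 endocannabinoid genes rose and 1 fell (camera adjusted p = 0.091, fry adjusted p = 3.53e-05), among them Dagla and Mgll at 1.10 ± 0.11 and 0.93 ± 0.08 (edgeR adjusted p = 5.69e-07 and 1.32e-07). These changes are against re-exposed saline, which stood apart. With saline without re-exposure as the control, the GABA-A, opioid, neuropeptide and endocannabinoid medians were -0.03, 0.11, 0.18 and -0.03. Camera called none of them (adjusted p = 0.311, 0.931, 0.105 and 0.671), and fry called the neuropeptide list only (adjusted p = 0.00494).

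The lists of immunity genes below were not called by camera in either comparison of zymosan with saline. Fry called zymosan recognition and complement and the cytokine list after re-exposure (adjusted p = 0.000682 and 0.000513). Of 25 genes of zymosan recognition and complement 2 rose and 4 fell without re-exposure, and of 23 tested 4 rose and 10 fell after re-exposure (camera adjusted p = 0.628 and 0.151). Tlr2 rose by 0.75 ± 0.21 and Tlr6 fell by 1.18 ± 0.15 without re-exposure (edgeR adjusted p = 0.0314 and 0.000271). After re-exposure Cfh, C1qa and Tlr7 fell by 1.98 ± 0.09, 1.42 ± 0.12 and 2.35 ± 0.19 (edgeR adjusted p = 1.58e-09, 2.14e-07 and 1.27e-07), in libraries where microglia markers had a median of -1.32. Of 26 interferon and MHC genes 1 rose and 4 fell without re-exposure (camera adjusted p = 0.111), with Ifit3 at -2.30 ± 0.34 (edgeR adjusted p = 0.000555). Cytokine and chemokine genes had 16 of 26 rising and 4 falling after re-exposure (camera adjusted p = 0.151), with Csf1 at 1.64 ± 0.08 (edgeR adjusted p = 1.91e-09). The medians after re-exposure were -0.48 for zymosan recognition and complement and 0.34 for cytokines. With saline without re-exposure as the control they were 0.24 and 0.09 (camera adjusted p = 0.453 and 0.762), and fry called neither (adjusted p = 0.127 and 0.242).

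Lists with fewer than 5 tested members were not tested. Of the long noncoding RNAs, Miat fell by 0.55 ± 0.07 without and rose by 1.96 ± 0.12 with re-exposure (edgeR adjusted p = 0.000283 and 1.05e-08), and Gas5 was at 0.48 ± 0.23 and -0.98 ± 0.12 (edgeR adjusted p = 0.167 and 5.38e-06). Miat stood at 232 and 162 CPM in saline and zymosan without re-exposure, and at 40.6 and 158 CPM with re-exposure. Its rise thus rests on the low level in re-exposed saline. Between the zymosan groups, re-exposed against not, Miat changed by -0.03 ± 0.09 and Gas5 by 0.65 ± 0.15 (edgeR adjusted p = 0.783 and 0.00242). Of the Y-linked genes Ddx3y was measured, at -0.24 ± 0.14 and -1.10 ± 0.15 (edgeR adjusted p = 0.245 and 1.3e-05), and whether its reads were kept apart from those of its X-linked paralog Ddx3x was not tested. The mitochondrially encoded genes are absent from both tables.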
